A study of Mus musculus with 9 samples.

How the data were processed

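RNA sequencing libraries were made from mouse gastrocnemius, the large calf muscle, after exercise. The labels put 5 libraries in a control group, with a Gprc6a gene flanked by loxP sites, and 4 in a knockout group, with the same gene and a Cre recombinase under the muscle creatine kinase (Mck) promoter. Per the labels' protocols, the mice were 3 months old, RNA with an integrity number of at least 6.7 was taken, and it was amplified with a NuGEN Ovation kit before Illumina library preparation. The labels do not say whether each library is a separate animal, so p-values measure the spread between these libraries.

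The deposited file holds raw read counts per gene symbol, whole numbers without normalization, for 23284 genes in 9 columns. Per the submitters' processing notes, the tools were bcl2fastq 1.8.4, Bowtie 0.12.7, TopHat (no version given) and HTSeq 0.6.1, with the mm9 build. The annotation, strand setting and filters are not given in the sources used here, so reads of overlapping or antisense genes could not be told apart, and genes with near-identical copies were treated as uncertain. The table gives no coordinates, and none are printed, since the reference at hand was GRCm38 (GENCODE M21 transcripts, and RefSeq symbols of GRCm38.p6). That reference was used only for gene names, transcript lengths and shared sequence. Total counts per library ranged from 19522947 to 25608659. A count of 0 allows up to 3 counts, or 0.117 to 0.154 CPM (counts scaled to a common library total) by library. These limits cover counting error only, since amplified reads are not independent molecules. Libraries of a group were not duplicates: chi-square per degree of freedom between pairs lay between 17.5 and 96.8.

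Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr on the groups with a minimum count of 10, which left 13198, and libraries were scaled by TMM. The quasi-likelihood F-test (glmQLFit and glmQLFTest, robust) compared knockout with control with no other term, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Log2 fold changes are knockout minus control. Their standard errors (SE) are the fold change divided by the root of F, and levels are CPM after TMM scaling, as mean ± SD.

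A total of 34 gene lists of pathways and cell types and 2 lists for checks were fixed before the data were examined. Of 823 listed symbols, 800 were found in the table, 15 of them through RefSeq synonyms. The 13 mitochondrially encoded messenger RNAs were not found under their listed symbols and were not analysed here. With that list included, 3 lists had fewer than 5 tested members, so 31 lists were tested. The lists were compared with all other tested genes by camera (limma 3.58.1) with a preset correlation between genes of 0.01. Camera with an estimated correlation and fry, which tests whether a list's genes move on balance one way, were run beside it. Members were also adjusted over the list alone. The genes named were fixed by rule: those named in advance, the 10 genes of smallest p per direction among the called genes with at least 1 CPM or, with fewer, the 5 of smallest unadjusted p per direction, up to 4 passing members or 3 of smallest unadjusted p in each list described, and the male and female transcripts. A few genes that this rule takes are not reported here. Which lists not past the threshold were described with members was decided after their values were seen. Single values were compared by two-sided exact permutation tests over the 126 splits of the libraries, whose smallest p is 0.0159, in scipy 1.17.1.

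The same edgeR steps were tested on simulated counts for 13198 genes with 200 changed, in 4 against 5 libraries. They recovered 28% of genes changed 1.5-fold, 76% at 2-fold, 86% at 3-fold and 96% at 4-fold, and called 13 unchanged genes. A list of 30 genes shifted by -0.4 was found, and 0 of 30 unshifted lists were called. The simulated genes varied independently, while members of a real list correlated by up to 0.881, so this does not show how often camera calls real lists falsely. The recovered shares also rest on 200 changed genes and leave out variation shared between genes, so they may not hold for the real fit. There Dnajb1, at a log2 fold change of -1.70, had an adjusted p of 0.9655 in edgeR.

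Alternatives fixed in advance were other scalings (RLE, upper quartile and totals only), DESeq2 1.42.0, limma-voom with quality weights, no filter or at least 50 counts in 4 libraries, a threshold of 0.1, non-robust fitting, each library left out in turn, a block on the label number, 1 surrogate variable (sva 3.50.0), and leaving out the 20 most abundant genes with ribosomal RNA. For lists, the 3 members of smallest p were also left out. Alternatives chosen after seeing the data removed each library's trend on transcript length (lowess, span 0.4) or on GC content, used the length slope as a covariate, used the legacy quasi-likelihood fit, left out the 3 libraries skewed to short transcripts, or left out the 2 control libraries richest in adipocyte transcripts. A transcript length was found for 98.9% of tested genes. Length, GC content and shared sequence were taken from the longest GENCODE M21 transcript of each symbol. That transcript may not be the one expressed in muscle. The length slope of a library is that of its log2 CPM deviations from the gene means (prior count 2) on log2 transcript length.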

Results

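Messenger RNA was measured by sequencing in gastrocnemius muscle of 3-month-old mice after exercise. The 5 control libraries came from mice with a loxP-flanked Gprc6a gene. The 4 knockout libraries came from mice that also carried Mck-Cre, which is active in striated muscle. Gprc6a encodes a G protein-coupled receptor for amino acids and osteocalcin. The comparison asks which transcripts differ in exercised muscle when the receptor gene is deleted in muscle fibres. By the labels only the knockouts carried Cre, and no group with Cre alone was included. An effect of Cre could therefore not be told apart from one of the deletion. No unexercised muscle was included, so the response to exercise itself was not measured. Total counts were 21666627, 25608659, 24691835, 21531958 and 20401633 in controls 1 to 5, and 22562162, 22533901, 22796548 and 19522947 in knockouts 1 to 4. The mean totals differed by less than the spread between libraries (22780142 ± 2242223, n = 5, against 21853890 ± 1558414, n = 4, exact permutation p = 0.571). The share of counts in Rn45s, a ribosomal RNA precursor, was 0.79% ± 0.213 in controls and 0.788% ± 0.31 in knockouts.

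The targeted gene, Gprc6a, had 0 counts in all 9 libraries, controls included. At these depths that allows at most 0.154 CPM (counts scaled to a common library total) per library, if reads of the gene were counted at all. The haemoglobin genes Hba-a1 and Hba-a2 also had 0 counts in every library, and sequence that Gprc6a shares with other genes was not examined. No fold change could be given for Gprc6a, and the counts do not check the knockout labels. The titles of the knockout samples name Gprc5a, another receptor gene, while their genotype and description name Gprc6a. Gprc5a stood at 8.1 ± 3.04 CPM in controls and 6.74 ± 2.14 CPM in knockouts, a log2 fold change of -0.25 (SE 0.30). That value was -0.05 without knockout 4, -0.09 without control 5, -0.11 without control 1, -0.39 without control 2 and 0.07 without control 5 and knockouts 3 and 4, the libraries skewed to short transcripts. Xist, the X-inactivation transcript of females, was present in every library (120 ± 35.5 CPM in controls), with a log2 fold change of -0.15. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had 0 counts in every library.

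In edgeR no single gene passed the threshold between knockout and control muscle, while DESeq2 called 3 genes lower. The genes of smallest p among those lower in knockouts were Dnajb1 and Fosb. Dnajb1, a co-chaperone of heat shock protein 70, averaged 115 ± 51.4 CPM in 5 controls and 35.6 ± 8.09 CPM in 4 knockouts, a log2 fold change of -1.70 (SE 0.30). Fosb, a subunit of the AP-1 transcription factor, averaged 127 ± 31.7 CPM against 51.3 ± 18.5 CPM (-1.31, SE 0.26). In each of these genes every knockout library lay below every control library.

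By edgeR's quasi-likelihood test, 0 of 13198 genes were higher and 0 were lower, and the smallest adjusted p was 0.965. At an unadjusted p under 0.05 there were 427 genes, 189 higher and 238 lower. That is 3.24% of tested genes, where the nominal chance rate is 5%. Other splits of the libraries gave a median of 337 such genes, and 43 of 100 splits, the real one included, gave at least 427. The groups did not overlap in 107 genes, or 0.81% where chance gives 1.59%. DESeq2 called 0 genes higher and 3 lower: Dnajb1 (adjusted p = 7.14e-05), Fosb (adjusted p = 0.00442) and Has1 (log2 fold change -1.63, adjusted p = 0.0301), a hyaluronan synthase named here because that count is small. With limma-voom 0 genes passed in either direction. The biological coefficient of variation between libraries was 18.7%.

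The other genes of smallest p that were lower in knockouts were Asb15 (log2 fold change -0.62, SE 0.13), a muscle ankyrin repeat and SOCS box protein, the potassium channel subunit Kcng4 (-0.42, SE 0.09) and the chaperone Hsp90aa1 (-0.71, SE 0.16). Those higher included Ppp1r3d, a glycogen-targeting subunit of protein phosphatase 1 (0.66, SE 0.16), Fkbp9 (0.34, SE 0.09), Micall2 (1.12, SE 0.28) and Rtp4 (0.67, SE 0.17). None of them passed the threshold in edgeR. Micall2 and Rtp4 stood at about 1 to 2 CPM.

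**Figure D1:**
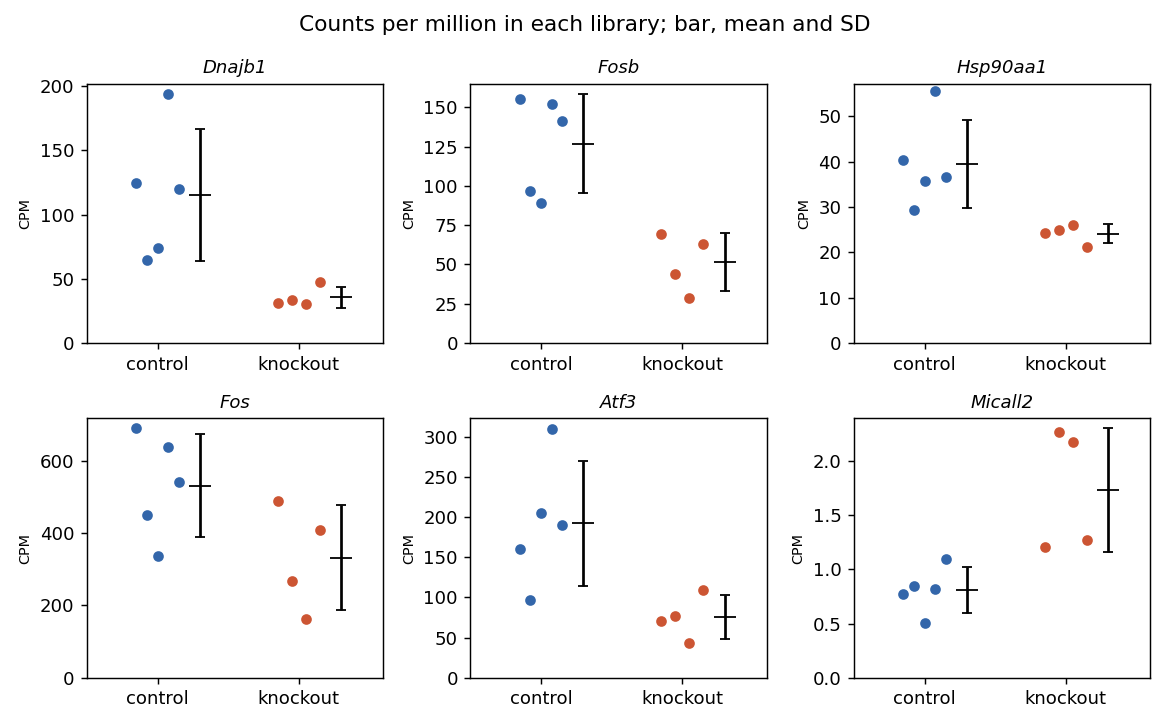
CPM (vertical axes, linear from 0) of 6 named genes, with a point for each control (blue) and knockout (orange) library and the mean ± SD beside them. All 4 knockout libraries lie below all 5 controls for Dnajb1, Fosb and Hsp90aa1, while Fos and Atf3 overlap between the groups, and no gene passed edgeR's adjusted threshold.

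Among genes named in advance for muscle fuel use and exercise, no value passed the threshold. Fos had a log2 fold change of -0.68 (SE 0.30) and Il6ra, the interleukin 6 receptor, of -0.71 (SE 0.24). Il6, a cytokine released by contracting muscle, fell under the count filter, with 18, 9, 9, 29 and 5 counts in controls and 3, 2, 3 and 6 in knockouts. Its level was 0.619 ± 0.447 CPM in 5 controls and 0.169 ± 0.103 CPM in 4 knockouts (exact permutation p = 0.0317, not adjusted, a test added once the filter had removed the gene). In the fit without the filter its log2 fold change was -1.89 (adjusted p = 0.938, edgeR). The fatty acid transporters Cd36 and Slc27a1 stood at -0.24 (SE 0.12) and -0.01 (SE 0.11), and the glucose transporter Slc2a4 at 0.19 (SE 0.12). Glycogen phosphorylase Pygm was at 0.04 (SE 0.12) and glycogen synthase Gys1 at -0.03 (SE 0.09). Ppargc1a was at -0.17 (SE 0.23), Pdk4 at 0.29 (SE 0.25), Lipe at -0.55 (SE 0.31, but 0.01 without controls 4 and 5, which stood at 94.0 and 69.8 CPM), Acadl at 0.04 (SE 0.14), Prkaa2 at -0.16 (SE 0.16), Mstn at -0.37 (SE 0.27) and Ckm at 0.19 (SE 0.16). With 1 library left out, Fos moved to -0.45 (without knockout 3), Pdk4 to -0.01 (without knockout 4) and Mstn to -0.22 (without control 4), -0.24 (without control 1) or -0.59 (without knockout 1). Over all alternatives Ckm ranged from -0.012 to 0.284, Prkaa2 from -0.25 to -0.01 and Ppargc1a from -0.412 to -0.016. Cpt1b, the muscle carnitine palmitoyltransferase, had only 23 counts over the controls and 28 over the knockouts. In the GENCODE M21 annotation of GRCm38, 93.0% of its 50-base words also stand in the read-through gene Gm44502, so its level is uncertain.

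By camera with the preset correlation, 12 of 31 lists passed, where other splits of the libraries gave a median of 9, and with an estimated correlation or with fry 0 lists passed. Immediate early genes, which are induced within minutes of stimulation, were lower in knockouts, with a median log2 fold change of -0.41 and 31 of 33 members below 0 (camera adjusted p = 1.2e-15, and adjusted p = 0.17 with an estimated correlation). In edgeR none of the 33 passed over all genes, and 2 passed when adjusted over the list alone, Fosb and the stress-induced factor Atf3 (-1.35, SE 0.33). DESeq2 called Fosb over all genes (adjusted p = 0.00442). Ier3 stood at -0.65 (SE 0.20). The mean log2 level of the list was 6.32 ± 0.162 in controls and 5.86 ± 0.28 in knockouts (exact permutation p = 0.0159, the smallest these groups can give, and adjusted p = 0.492 over 31 lists). For other lists described below, the same exact permutation test gave p = 0.0635 for heat shock, 0.0952 for erythroid, 0.27 for adipocyte, 0.397 for fibroblast and 0.54 for ribosomal protein genes.

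Heat shock and unfolded protein response genes had a median of -0.06, with 16 of 26 members below 0 (camera adjusted p = 0.00205, and adjusted p = 0.435 with an estimated correlation). Adjusted over the list alone, 4 of its members were lower: Dnajb1, Hsp90aa1, Hspa1b (-1.61, SE 0.37) and Hspa1a (-1.52, SE 0.40). None passed over all genes in edgeR, while DESeq2 called Dnajb1 (adjusted p = 7.14e-05). Hspa1a and Hspa1b share 60.3% and 62.3% of their 50-base words with other genes, mainly each other, so their reads could not be told apart with certainty. The call was lost without the 3 members of smallest p (median -0.04, camera adjusted p = 0.455), without control 5 (median 0.01, adjusted p = 0.168) and without controls 4 and 5 (median 0.03, adjusted p = 0.173), the controls richest in adipocyte transcripts.

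Adipocyte transcripts were lower on average in knockouts, with a median of -0.67 and 17 of 18 members below 0 (camera adjusted p = 2.26e-08, and adjusted p = 0.435 with an estimated correlation). The list's mean log2 level was 5.67 ± 0.718 in controls and 5.12 ± 0.247 in knockouts (exact permutation p = 0.27). It was 4.89, 5.19 and 5.39 in controls 1 to 3, 6.51 and 6.34 in controls 4 and 5, and 5.34, 4.85, 5.33 and 4.98 in knockouts 1 to 4. Scd1, the stearoyl-CoA desaturase, stood at -1.43 (SE 0.46), the lipid droplet protein Plin1 at -1.07 (SE 0.40), and Ucp1, the uncoupling protein of brown fat, at -3.75 (SE 1.39). Ucp1 was at 16.6 CPM in control 4 and 7.03 CPM in control 5, and at 0.692 CPM or less in the other 7 libraries. Scd1 was at 1359 and 859 CPM in these controls. Without both of them the list's median was -0.15 (camera adjusted p = 0.516). Without control 4 alone it was -0.33 and without control 5 alone -0.41, and the call held. No member passed over all genes or over the list alone. The immediate early list without both controls had a median of -0.33 (camera adjusted p = 3.02e-06).

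**Figure D2:**
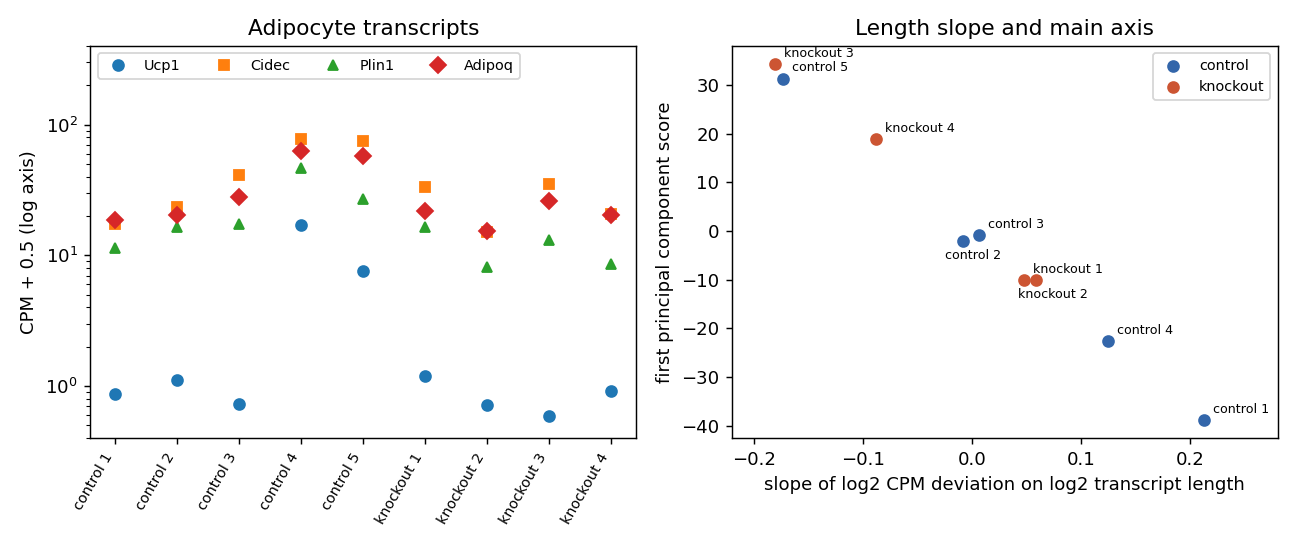
Left, CPM plus 0.5 (log axis) of 4 adipocyte transcripts in each of the 9 libraries; controls 4 and 5 are highest for each, with Ucp1 at 16.6 and 7.03 CPM. Right, the first principal component score of each library against its slope on transcript length, controls blue and knockouts orange, where the groups interleave along a falling line.

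Erythroid transcripts were higher in knockouts, with a median of 0.68 over 6 tested members (camera adjusted p = 0.00414, and adjusted p = 0.388 with an estimated correlation). Adjusted over the list alone, 3 were higher, among them the haemoglobin gene Beta-s (1.39, SE 0.44) and Alas2, the erythroid haem synthesis enzyme (1.24, SE 0.47). Beta-s was at 335 CPM in knockout 3 and 127 CPM in knockout 4, against 61.9 and 61.4 CPM in knockouts 1 and 2 and 55.6 ± 7.64 CPM in 5 controls. The list no longer passed without control 5 (median 0.60, adjusted p = 0.101), and without knockout 3 its median was 0.26 (adjusted p = 0.00655), with Beta-s at 0.58 and Alas2 at 0.46. Without the 3 members of smallest p its median was -0.08 (adjusted p = 0.912), and without control 5 and knockouts 3 and 4, the libraries skewed to short transcripts, it was -0.03 (adjusted p = 0.703) and Alas2 stood at -0.03. Fibroblast and extracellular matrix genes had a median of 0.10, with 19 of 23 above 0 (camera adjusted p = 0.000331, and adjusted p = 0.435 with an estimated correlation). The collagens Col3a1, Col5a1 and Col6a2 stood at 0.51 (SE 0.17), 0.38 (SE 0.14) and 0.25 (SE 0.12). Without knockout 2 that call was lost (adjusted p = 0.258).

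A further 7 lists passed with the preset correlation. Cell cycle genes, all near or under 4 CPM where named, had a median of 0.21 (adjusted p = 0.0189, and adjusted p = 0.435 with an estimated correlation), and of 0.093 to 0.525 over the alternatives. Their named members went apart: Top2a was at 1.46 (SE 0.37), Mcm5 at 0.50 (SE 0.20) and Ube2c at -1.40 (SE 0.34). Adjusted over the list alone, 1 member was higher and 1 lower, and the fry test of change in either direction gave an adjusted p of 0.0152. Circadian clock genes had a median of -0.16 (adjusted p = 0.0222, and adjusted p = 0.388 with an estimated correlation), with Gm129 (Ciart) at -1.13 (SE 0.43), Rora at -1.07 (SE 0.42) and Npas2 at 1.55 (SE 0.70, but 0.58 without knockout 2 and 2.42 without control 2). Genes of insulin, AMPK and mTOR signalling had a median of -0.09 (adjusted p = 0.0222, and adjusted p = 0.435 with an estimated correlation), with Pik3r1 at -0.53 (SE 0.21) and Rptor at -0.21 (SE 0.12). Mitochondrial biogenesis genes had a median of -0.09 (adjusted p = 0.0409, and adjusted p = 0.388 with an estimated correlation), with Ppara at -0.56 (SE 0.21), Nrip1 at -1.29 (SE 0.56) and Ppargc1b at -0.53 (SE 0.26). Fast fibre proteins had a median of 0.09 (adjusted p = 0.026, and adjusted p = 0.689 with an estimated correlation), with Myl1 at 0.19 (SE 0.09), Tnnc2 at 0.26 (SE 0.19) and Mylpf at 0.18 (SE 0.13), and the median was -0.02 (adjusted p = 0.538) without the 3 libraries skewed to short transcripts. Interferon response genes had a median of 0.10 (adjusted p = 0.0425, and adjusted p = 0.484 with an estimated correlation), with Xaf1 at 0.90 (SE 0.37), Gbp3 at -0.33 (SE 0.23, and -0.45 to -0.145 over the alternatives) and Mx2 at 0.61 (SE 0.45). Ribosomal protein genes had a median of 0.10 (adjusted p = 0.00576, and adjusted p = 0.835 with an estimated correlation), with Rpl3 at -0.33 (SE 0.20, and -0.485 to 0.032 over the alternatives), Rpl19 at 0.24 (SE 0.17) and Rps23 at 0.37 (SE 0.28), and many share sequence with other genes. Their mean level was highest in the 3 libraries skewed to short transcripts, and their median was -0.03 with a surrogate variable (adjusted p = 0.289), -0.01 with the length slope as covariate (adjusted p = 0.671) and 0.02 with the length trend removed (adjusted p = 0.446). Each of these 7 calls was lost without single libraries. Cell cycle genes lost it without control 3 or knockout 2 (adjusted p up to 0.255), clock genes without control 4, knockout 2 or knockout 3 (up to 0.0914), and interferon genes without control 1, 4 or 5 or knockout 4 (up to 0.474). Insulin signalling lost it without control 1 or 4 or knockout 3 or 4 (up to 0.105), as did ribosomal proteins (up to 0.424). Fast fibre proteins lost it without control 3 or 5 or knockout 3 or 4 (up to 0.298), and mitochondrial biogenesis without control 1, 3 or 5 or knockout 2 or 4 (up to 0.231).

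Among fuel and contractile lists that did not pass, the median was 0.05 for glycogen and glycolysis (adjusted p = 0.326, Gbe1 at -0.30, SE 0.14), 0.00 for fatty acid uptake and oxidation (adjusted p = 0.881, Lpl at -0.23, SE 0.18), where the mean was -0.01, and 0.06 for the respiratory chain (adjusted p = 0.0611, Sdha at -0.09, Ndufc2 at 0.17 and Cycs at 0.16). The respiratory chain passed upward without control 3 (0.07, adjusted p = 0.0142), control 5 (0.20, adjusted p = 1.36e-07), knockout 1 (0.12, adjusted p = 0.00213) or knockout 2 (0.13, adjusted p = 0.000842), but downward with a surrogate variable (-0.10, adjusted p = 6.83e-08) or the length covariate (-0.07, adjusted p = 2.32e-05). Glycogen and glycolysis passed without knockout 2 (0.12, adjusted p = 0.0117), and fatty acid genes passed at -0.07 with a surrogate variable and at 0.10 without controls 4 and 5. Slow fibre proteins had a median of -0.12 (adjusted p = 0.402, Atp2a2 at -0.36, Csrp3 at 0.33 and Myh7 at -0.31). They passed without knockout 2 (-0.33, adjusted p = 0.00156, with Atp2a2 at -0.64 and Myh7 at -0.67) or control 1 (-0.20, adjusted p = 0.0337), but without the 3 libraries skewed to short transcripts the median was 0.04 (adjusted p = 0.593), Atp2a2 stood at -0.11 and Myh7 at -0.04. Without knockout 3, Csrp3 stood at 0.13, Atp2a2 at -0.22 and Myh7 at -0.15. Cyclic AMP signalling genes had a median of -0.07 (adjusted p = 0.0825), with Prkar2b at -1.66 (SE 0.63), which followed controls 4 and 5 at 39.7 and 19.4 CPM, and Adcy2 at -0.34 (SE 0.15). Muscle secreted factors had a median of -0.02 (adjusted p = 0.808, Cxcl1 at -1.06, Chi3l1 at -0.58 and Apln at 0.31). Cxcl1 was at 4.4 CPM in knockout 4 and 0.806 to 1.3 CPM in the other knockouts, and stood at -1.85 without it, while Chi3l1 stood at -0.35 without control 3 and Apln at 0.47 without knockout 1.

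**Figure D3:**
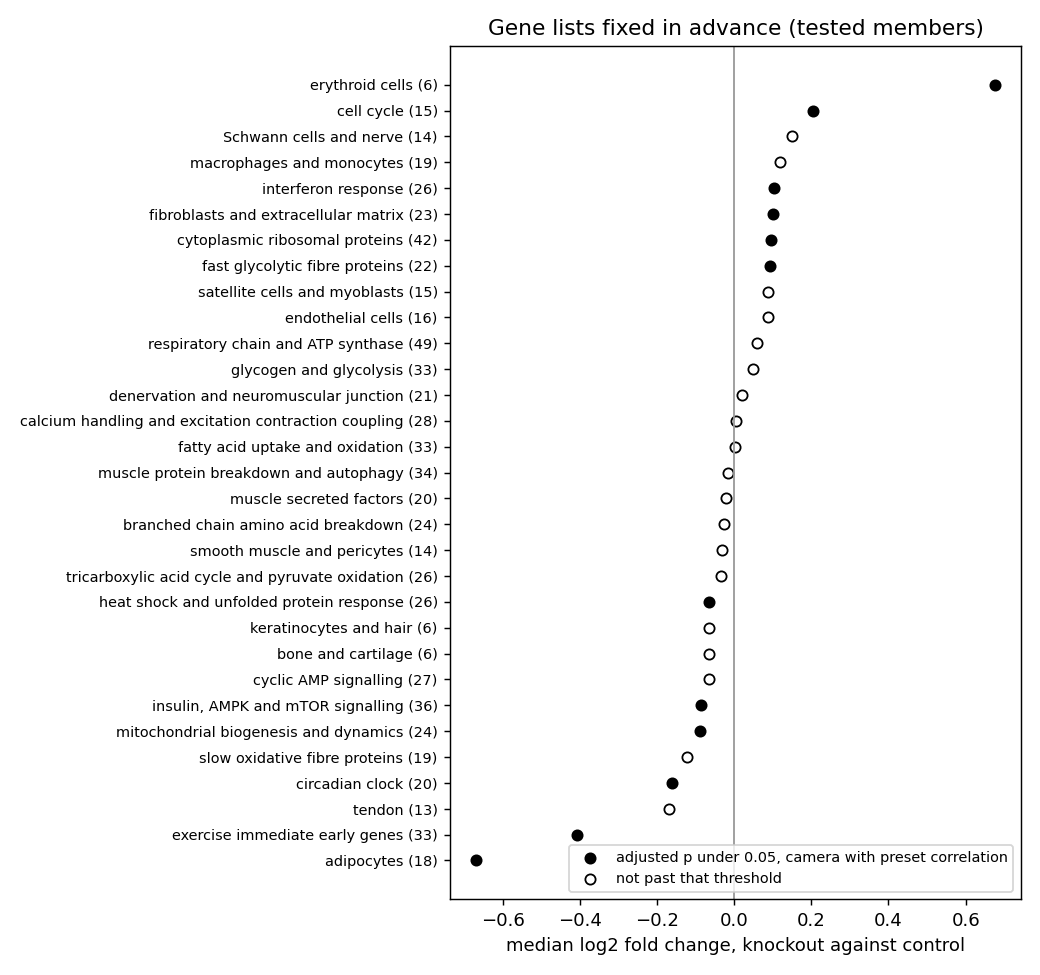
Median log2 fold change, knockout against control (horizontal axis), of each of the 31 tested gene lists, with the number of tested members in brackets. Filled points passed camera with the preset correlation and open points did not. Adipocytes (-0.67) and immediate early genes (-0.41) lie lowest and erythroid cells (0.68) highest, and no list passed with an estimated correlation.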

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

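The tests of leukocyte content, of adipose tissue for the adipocyte list, of genotype on the main axis and of the smallest p of any list were chosen only after results were seen, as were the fits without the length trend or without controls 4 and 5. A library that lay far from the rest of its group was found in 12 of 200 groups of values, or 6%, where chance gives about 5%. The gap divided by the range was 0.92 for the total of knockout 4 (19522947 counts, others 22533901 to 22796548) and 0.834 for the GC slope of knockout 3 (2.12, others -0.431 to -0.0078). Among list means it was 0.861 for immediate early genes in knockout 3 (5.44, others 5.95 to 6.03), 0.867 for mitochondrial biogenesis in knockout 1 (5.4, others 5.31 to 5.32) and 0.92 for interferon genes in knockout 4 (2.03, others 1.76 to 1.78). Among genes it was 0.882 for Gprc5a in knockout 4 (3.55 CPM, others 7.41 to 8.16), 0.864 for Mstn in knockout 1 (97.1 CPM, others 55.9 to 60.3) and 0.945 for Rtp4 in knockout 3 (2.04 CPM, others 1.8 to 1.82). It was 0.824 for Gbe1 in control 2 (67.0 CPM, others 95.5 to 103), 0.878 for Npas2 in knockout 2 (5.9 CPM, others 1.08 to 1.38), 0.956 for Xaf1 in knockout 3 (4.27 CPM, others 7.0 to 7.16) and 0.766 for Gbp3 in control 3 (3.18 CPM, others 1.79 to 2.06).

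Immediate early genes were lower in knockout muscle by camera with the preset correlation. The call was lost with an estimated correlation (camera adjusted p = 0.17) and with fry (adjusted p = 0.443). Removing each library's length trend left the median at 1.12 times its size, leaving out any single library left at least 0.664 of it (knockout 3 out), and leaving out controls 4 and 5 left 0.811, so length bias, a single library or adipose tissue in those controls was argued against as the whole cause. The 26 tested genes of the leukocyte lists had a median log2 fold change of 0.07 (0.0691). Of these genes 19 were macrophage and monocyte genes, so the median argues against fewer macrophages and monocytes. It cannot speak for neutrophils or lymphocytes, whose lists had too few tested members. Of 100 splits of the 9 libraries, the real one counted here and below, 2 gave this list a camera p as small as the real 3.87e-17, the other having 7.57e-19, but this was the list of smallest p among 31, and in 36 of 100 splits some list reached a p as small (smallest of the others 2.31e-31), so chance is not excluded once the choice of list is counted. An effect of genotype may still contribute, as a hypothesis, and differences in exercise, handling or time to dissection, which the labels do not give, were not tested. The sample descriptions also carry a GP number of unstated meaning: 2, 4, 7, 8 and 9 in controls 1 to 5, and 1, 3, 5 and 6 in knockouts 1 to 4. The highest of these numbers all fell on controls, with 8 and 9 on controls 4 and 5, the controls richest in adipocyte transcripts. The adipocyte and heat shock calls were lost without both of these controls. An effect of that order was not tested for any list.

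Adipocyte transcripts were lower in knockout muscle by camera with the preset correlation, a call lost with an estimated correlation (camera adjusted p = 0.435) and with fry (adjusted p = 0.532). Leaving out controls 4 and 5 left 0.223 of the median, but they were picked for these transcripts, so a fall was bound to follow and does not decide whether adipose tissue in those samples was the cause. A total of 22 of 100 splits gave a camera p as small as the real 1.46e-09 (smallest of the others 8.76e-31), so chance cannot be excluded. All 18 members were fixed as adipocyte genes in advance, and Cd36, also in the fatty acid list, is expressed in muscle too. Scd1 stood at 201 to 354 CPM in the libraries other than controls 4 and 5, so its reads may not come from adipocytes alone. Whether genotype alters muscle fat was not tested by other means.

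The main axis of variation between libraries, 39.5% of the variance, followed transcript length: its scores correlated with the length slope with Pearson's r = -0.998 (permutation p = 6e-05) and Spearman's rho = -0.983 (permutation p = 0.00014) over 9 libraries, and with r = -0.995 (exact permutation p = 0.00119) without the 2 farthest. Genotype did not separate the scores (-6.64 ± 26.4 against 8.3 ± 22.1, exact permutation p = 0.397, adjusted p = 0.8 over 7 quality values), and the ranges overlapped. A difference in RNA integrity or amplification between libraries is a candidate explanation of the axis, but the labels give neither per library, so they were not tested. The correlation with the length slope comes from the same counts and cannot tell whether either was the cause. The ends of the axis also differed otherwise. Control 1, of lowest score, had a GC slope of -2.06 and 0.6% of counts in Rn45s, and knockout 3, of highest score, had 2.12 and 1.01%. Rn45s held 1.01 to 1.14% of counts in control 5 and knockouts 3 and 4, of highest score, and at most 0.825% in the others. The GC slope mostly rose along the axis too, from -1.58 in control 4 to 1.03 in control 5. Exceptions were control 2 (1.37) and knockout 4 (-0.0078). The axis was thus not particular to transcript length, though no test of GC content or Rn45s was run.

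A real count of 0 genes is reached by 100 of 100 splits whatever the data, so the splits say nothing of it. The highest count in another split was 1680, for a split that set controls 2 and 5 and knockouts 3 and 4 apart. These libraries had both the lowest slopes on transcript length and the highest slopes on GC content. The split does not tell length and GC content apart, and neither was tested as its cause. As many lists as the real 12 passed in 25 of 100 splits (highest other 16), so chance is not excluded for that count. For heat shock genes, 13 of 100 splits gave a camera p as small as the real 0.000265 (smallest of the others 6.74e-09).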

How the results depend on the processing

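Alternatives named for length, GC content, the legacy fit and the short-skewed or adipose-rich libraries were chosen after seeing the data. The count of genes stayed at 0 in both directions under 25 of the 27 alternatives that test genes, including each library left out; DESeq2 called 3 lower and the replicate block 1 lower. The block used libraries 1 to 4 of each group, and same-numbered libraries correlated at 0.419, 0.037, 0.081 and -0.067, so the numbers share no evident pairing. Gprc6a had no counts, so no alternative gave it a value. The 12 lists became 16 at an adjusted p under 0.1, 14 with a surrogate variable or without knockout 1, and 13 without the filter, with the length covariate or without control 2. They became 5 without the 3 members of smallest p, 6 with the length trend removed, 7 without the 3 short-skewed libraries, 8 with the stricter filter or without control 4 or knockout 4, 9 to 11 in 8 others, and 0 with an estimated correlation or fry. With an estimated correlation and with fry the medians are those given before (-0.408 for immediate early, -0.064 for heat shock, -0.668 for adipocyte genes) and the adjusted p rose to 0.17 and 0.443, 0.435 and 0.532, and 0.435 and 0.532. Heat shock genes also lost the call without the 3 smallest-p members (-0.041) and without the adipose-rich controls (0.031), and ranged from -0.136 to 0.01 with 1 library out. Adipocytes had -0.149 without those controls. Without the short-skewed libraries signs turned for fast fibre proteins (-0.024), Gprc5a (0.074), Ckm (-0.012), Pygm (-0.101), Alas2 (-0.034), Rpl3 (0.032) and Mx2 (-0.064). Ribosomal proteins turned with a surrogate variable (-0.031) and the length covariate (-0.010), Acadl with these (-0.029 and -0.004), the length trend removed (-0.017) and limma-voom (-0.006), and Cycs with a surrogate variable (-0.026). Erythroid genes turned without the 3 smallest-p members (-0.077), and cell cycle genes turned in the test, at a median of 0.093, with the stricter filter. Slc27a1 turned with upper quartile scaling (0.016) and without the adipose-rich controls (0.052), as did Gys1 (0.021, and 0.013 with the block) and Lipe (0.007). With 1 library out, Slc27a1 ranged from -0.064 to 0.046, Pygm from -0.012 to 0.119, Gys1 from -0.07 to 0.014, Pdk4 from -0.009 to 0.425, Acadl from -0.055 to 0.124, and the difference in the percentage of Rn45s from -0.103 to 0.105. Over all genes named, 1821 gene values kept their sign and side of the threshold, 24 turned and 3 newly passed; where signs turned the cause was not tested. In simulated counts at these depths 28% of 1.5-fold changes were recovered, so most changes of that size would be missed. The simulation had 200 changed genes that varied independently, so its higher recovery of larger changes may not hold for these libraries.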

Other observations

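The remaining lists, given here as camera with the preset correlation tested them, did not pass. Medians were 0.15 for Schwann cells and nerve (adjusted p = 0.0569), 0.09 for satellite cells and myoblasts (adjusted p = 0.0978), 0.09 for endothelial cells (adjusted p = 0.134) and 0.12 for macrophages and monocytes (adjusted p = 0.213). Tendon stood at -0.17 (adjusted p = 0.402), smooth muscle and pericytes at -0.03 (adjusted p = 0.758) and bone and cartilage at -0.07 (adjusted p = 0.547). The tricarboxylic acid cycle stood at -0.03 (adjusted p = 0.469), muscle protein breakdown and autophagy at -0.02 (adjusted p = 0.488), branched chain amino acid breakdown at -0.03 (adjusted p = 0.601) and calcium handling at 0.01 (adjusted p = 0.758). The denervation and neuromuscular junction list had a median of 0.02 and a mean of -0.09, and its test pointed down (adjusted p = 0.76). Keratinocyte and hair genes had a median of -0.07 while their test pointed up (adjusted p = 0.326). Their mean log2 level was 4.15 in control 2, 3.53 in knockout 2 and 2.35 in knockout 1, and 0.667 to 0.903 in the other libraries. This list was not among those searched for outlying libraries. The neutrophil and the lymphocyte lists had too few tested members, and the mitochondrially encoded messenger RNAs were not found under their listed symbols. With 1 library left out, calls were gained by Schwann cells (without control 3 or 5 or knockout 2, adjusted p down to 0.00329), macrophages (without control 2 or knockout 1, down to 0.0317), satellite cells (without knockout 3, 0.0181) and keratinocytes (without knockout 3 or 4, down to 6.99e-05). The tricarboxylic acid cycle, protein breakdown and branched chain lists passed downward with a surrogate variable (adjusted p = 0.014, 0.0149 and 0.0149) and with the length covariate (adjusted p = 0.0237, 0.0337 and 0.0221).

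The comparison of shared sequence was added after low levels of some abundant genes were seen. Among 159 glycolytic, fatty acid, respiratory and ribosomal genes with a GENCODE M21 transcript, the 19 under 10 CPM shared a median of 38.2% of their 50-base words with another annotated gene, and the 140 others 0.15%. The difference in means, not medians, was tested (permutation p = 2e-05, the smallest that 100000 permutations can give). Of those 19, 14 were ribosomal protein genes, while 111 of the 140 were metabolic, so much of this contrast lies between the kinds of gene. Among ribosomal protein genes alone the medians were 44.2% under 10 CPM and 32% above, a difference not tested. Of the 5 metabolic genes under 10 CPM, 2 (Gapdh and Cpt1b) shared over 20%, as did 11 of the 111 others, and Angptl4, Pgm1 and Ppp1r3b shared 0%, 0% and 0.2%. Gapdh, abundant in muscle, stood at 5.13 CPM in controls, with 27.2% of its words shared with 213 other genes. The haemoglobin genes Hba-a1 and Hba-a2 had 0 counts in every library, with 67.5% and 86.9% shared. The median length of the longest annotated transcript was alike, at 1877 bases under 10 CPM and 1866 above. That transcript, of 3289 bases for Gapdh, may not be the one expressed. The lengths and shared percentages therefore need not hold for the messenger RNAs that were counted. Levels of genes that share much sequence are uncertain in this table, and the counting settings that would decide how shared reads were treated are not given in the sources used here.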
